A study of Mus musculus with 6 samples.

How the data were processed

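Testis RNA of 6 mice was labelled with digoxigenin and hybridised to 1-colour arrays, per the labels' protocols. The labels give each array its own animal, genotype and diet, and no batch, slide or scan date, so no batch could be tested. Replicates of different groups are not paired.

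The deposited table of raw values holds, per the file headers, a signal intensity and a signal-to-noise score for each of 33012 probes on each array. The scanner software and its settings are not given in the sources used here. The values themselves showed that a background had already been taken off. Between a signal-to-noise of 1 and 10 the signal divided by its signal-to-noise was nearly constant within an array, so no constant background showed in that range. Brighter probes were left out of this check. Dimmer probes kept a positive signal, with a median of 116 to 235 per array at a signal-to-noise between -1 and 1, so differences that reach this floor are compressed. A second deposited table, of the authors' processed intensity values, equals the raw signal divided by 1 constant per array close to that array's median, on a linear scale, with no centring of genes and a median of 1 on every array. It served as an alternative. There were 0 further per-sample columns left out. At the bright end, the raw signal of the protamine gene Prm2 was 784705 to 1031573, with 784705 on the dim array, while on that array Clu fell from 959121 on the other wild-type array to 389779 and Gsg1 from 911709 to 425585. Prm1, another protamine gene and named outside the rule given below, read 8.13e+05 to 8.73e+05, with 8.55e+05 on the dim array. The brightest signal of an array was 1.74e+06 to 3.13e+06, so no ceiling common to all probes lay at that level. Why Prm1 and Prm2 did not follow the dim array, and whether their probes were saturated, was not tested. Both genes are in the elongating spermatid list, which carries this limit.

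Raw signals were taken as deposited, without further background correction, as log2 values and quantile-normalised between arrays with limma 3.58.1 in R 4.3.3. Probes were kept when the signal-to-noise was at least 3 on both arrays of at least 1 group, which left 16015 probes. Of these, 12990 were detected on all 6 arrays. A linear model with 1 mean per group and 1 shared spread was fitted to all 6 arrays with lmFit and eBayes, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Errors are SDs of the 2 arrays of a group or the SE of the moderated difference. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so p-values come from limma alone. A probe not detected on either array of a group has only a bound there. Its fold is given as at least the ratio of the brighter group's mean to the dim group's, where a dim value below the lowest detected signal of its array is set to that signal, on the normalised log2 scale.

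Gene names came from the platform's annotation, updated through the gene identifiers of the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. Of all probes, 14411 had 1 gene symbol, 247 had several and 18354 had none listed. Probes with several symbols name no gene here. Of the kept probes, 8499 had 1 symbol and stood for 8267 genes, and 7516 name no gene. Where a gene had several probes, as for 224 genes, the one with the highest mean log2 signal over all arrays stood for it; 0 genes had probes called in opposite directions.

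Before the data were examined, 28 gene lists were fixed for the cell types of the testis and its interstitium, tissues that could be carried along, sterol and lipid pathways, stress responses, housekeeping groups and the genes next to Abcg8. They held 578 genes, of which 440 were on the array and 335 were tested. Lists with at least 5 measured genes were tested, 25 in all, with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists within a comparison. The remaining lists were too short: interferon response with 3 measured genes, the erythroid list with 2 and epididymis with 4. In camera a list is set against all other genes, and in fry it is tested by itself.

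The rule for named genes was also fixed then. It takes Abcg8 and Abcg5 in every comparison, then up to 12 genes in each direction with the largest change among those that pass, do not overlap between the groups, are detected on both arrays of the higher group and have a proper gene name. Where fewer than 5 pass, genes with the lowest p fill the direction to 5 and are said not to pass. Up to 4 members with the lowest p come from each passing list and from the sterol, Leydig, Sertoli, germ cell and macrophage lists. Genes named outside the rule are said to be so. Alternatives tried were median scaling, the authors' processed values, normexp background correction with an offset of 50, other filters on dim probes, an intensity trend or a robust fit in the prior variance, array weights, fits to the compared groups alone, and leaving out each array in turn. When an array is left out, the lone array of its group is assumed to vary like the others.

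The fits were tested on simulated data with spreads drawn around the intensity trend fitted to the real probes. This favours the fit with that trend, so the simulations cannot decide between the 2 fits. In 20 simulations of knockout against wild-type over 16015 probes, 27.0% of 100 probes changed 2-fold and 74.5% of 100 changed 4-fold were called, with 5.55 false calls per simulation, and with an intensity trend 64.0% and 85.7% were called with 7.95 false calls. A list of 13 genes shifted by 0.5 log2 units was called by camera in 20 of 20 simulations over 8267 genes, and 2 of 480 tests of unshifted lists were called. The simulated genes were independent of each other, so these counts do not test camera where the members of a list are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.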

Results

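Gene expression was measured in whole testes of 6 adult male mice, 10 to 12 weeks old, with 1 array per mouse and 2 mice in each of 3 groups. The groups were wild-type mice on chow, Abcg8 knockout mice on chow, and Abcg8 knockout mice on chow with 0.005% ezetimibe. Abcg8 encodes sterolin-2, which pairs with the product of Abcg5 to export cholesterol and plant sterols from liver and gut cells. Ezetimibe blocks the uptake of sterols from the gut. The median raw signal was 678 and 258 on the wild-type arrays, 611 and 515 on the knockout arrays and 583 and 614 on the ezetimibe arrays, so that wild-type replicate 2 was the dimmest array. Between 15371 and 16632 of the 33012 probes were detected on an array. The normalised log2 signals of the 2 arrays of a group correlated across probes with r = 0.991 for wild-type and 0.994 for each knockout group, and genes are not independent replicates. The first principal component held 39.3% of the variance and set wild-type replicate 2 apart, at 53.6 against values from -17.3 to 0.73 on the other 5 arrays. The number of arrays limits the precision: the median SE of a log2 difference between groups was 0.14.

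The first comparison asked how testes of knockout mice differed from wild-type testes. The probe for Abcg8, the targeted gene, was brighter on the arrays labelled knockout, against the direction of the labels. Its log2 signal was 10.31 ± 0.03 (SD, n = 2) on the wild-type-labelled arrays, 14.19 ± 0.22 (SD, n = 2) on the knockout-labelled arrays and 14.41 ± 0.01 (SD, n = 2) on the knockout-labelled arrays with ezetimibe. In raw signal, the wild-type-labelled arrays read 1715 and 569, the knockout-labelled arrays 20013 and 22134, and those with ezetimibe 25697 and 24767. The difference between knockout-labelled and wild-type-labelled arrays was 3.88 log2 units (SE 0.13), or 14.7-fold, with adjusted p = 0.0177 from limma. The position of this probe (570984) relative to the altered part of the gene is not given in the sources used here, so the probe may check nothing about the labels, and directions between genotypes below rest on the labels alone. The partner gene Abcg5 was not detected on any array and was not tested.

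Apart from Abcg8, a single probe changed between knockout-labelled and wild-type-labelled testes. Probe 637213, for which no gene was listed, read 12.71 ± 0.14 (SD, n = 2) in wild-type-labelled testes and was not detected on either knockout-labelled array. It was lower by at least 22.2-fold (limma adjusted p = 0.0291). These 2 probes, 1 higher and 1 lower, were all that limma called among 16015 probes, while 1440 had an unadjusted p under 0.05 and 801 would by chance. Further genes with low p did not pass. Ston1, an endocytic adaptor gene, differed by -2.25 log2 units (SE 0.17, limma adjusted p = 0.163), and Entpd4, a nucleotide-hydrolysing enzyme, by -1.16 (adjusted p = 0.163). Ston1 lies near the targeted gene, with 16 measured genes between it and Abcg8 on chromosome 17. Whether its difference is tied to the targeted region was not tested. Ctla2a differed by -1.28, Riok2 by -1.16, Wdfy1 by 1.48 and Egfl7, a secreted endothelial factor, by 1.39, all with adjusted p of 0.203 or more. The immediate early gene Egr1 was not detected on the knockout-labelled arrays and was at least 3.40-fold lower there (limma adjusted p = 0.26), and the olfactory receptor genes Olfr700 and Olfr1404 were not detected in wild-type-labelled testes and were at least 2.48-fold and 2.77-fold higher in knockout-labelled testes (adjusted p = 0.164 and 0.316).

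Collagen and other matrix genes were higher as a group in knockout-labelled testes. All 13 measured members of the extracellular matrix and fibroblast list lay above 0, with a mean difference of 0.54 log2 units (camera adjusted p = 2.53e-05, and adjusted p = 0.656 with an estimated correlation). Of these 13 genes, 0 passed among all probes and 4 passed when adjusted over the list alone: Col3a1 at 0.81 (SE 0.17), Col1a2 at 0.63 (SE 0.14), Col1a1 at 1.08 (SE 0.24) and Col6a1 at 0.49 (SE 0.12). The list's mean on each array, relative to the mean of all 6, was -0.10 and -0.32 on the wild-type-labelled, 0.37 and 0.29 on the knockout-labelled and -0.12 and -0.12 on the ezetimibe arrays. Hba-a1, an alpha globin gene of red cells, chosen after its values were seen, read 15.93 and 15.91 on the wild-type-labelled arrays, 18.29 and 17.26 on the knockout-labelled arrays and 14.99 and 15.69 on the ezetimibe arrays. The difference of Hba-a1 between knockout-labelled and wild-type-labelled arrays was 1.85 log2 units (limma adjusted p = 0.435). Alas2, which makes haem in red cells, differed by 0.27 (adjusted p = 0.612), and the embryonic globin gene Hba-x went the other way, not detected in knockout-labelled testes and at least 3.06-fold lower (adjusted p = 0.409), both also chosen after their values were seen.

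Genes of sterol handling gave no call beyond Abcg8 in this comparison. Of 14 measured cholesterol synthesis and uptake genes, 4 lay above 0 and 10 below, with a mean of -0.17 log2 units (camera adjusted p = 0.359). Tm7sf2, a sterol reductase, differed by -0.55 (SE 0.14), Msmo1 by -0.45, Insig1 by -0.46 and Pmvk by 0.25, and 0 of the 14 passed, adjusted over the list alone included. The 8 LXR targets and sterol efflux genes had a mean of 0.56 (camera adjusted p = 0.359), which rested on Abcg8, since the other 7 had a mean of 0.09. Among them, Apoe differed by 0.24 (0.07 without wild-type replicate 2 and 0.41 without wild-type replicate 1), Apoc1 by 0.27 and Nr1h3, the LXR alpha gene, by -0.11, and the last turned to 0.015 under median scaling. Adjusted over the list alone, Abcg8 was the 1 member that passed.

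Markers of the testicular cell types did not pass as lists. The Leydig cell list of 12 genes split 6 above and 6 below 0 (camera adjusted p = 0.733), with the side-chain cleavage enzyme Cyp11a1 at 0.45 and Hsd3b6 at -0.48. The Sertoli cell list had 10 of 15 genes above 0 (adjusted p = 0.423), with the FSH receptor gene Fshr at 0.59 (0.38 to 0.78 over all alternatives). The spermatogonia list had 8 of 13 above 0 (adjusted p = 0.457), the spermatocyte list 10 of 18 (adjusted p = 0.644), the round spermatid list 7 of 20 (adjusted p = 0.547) and the elongating spermatid list 6 of 18 (adjusted p = 0.359). Members of these germ cell lists read 1.26 for Sohlh1 (0.90 to 1.62 over all alternatives), 0.36 for Msh5 (0.22 to 0.50 over all alternatives), 0.31 for Spaca1 and -0.29 for Gsg1. Sohlh1 was not detected on wild-type replicate 2. Sall4, a spermatogonia gene, was detected on the knockout-labelled arrays without ezetimibe alone, at a signal-to-noise of 3.09 and 3.71, so the size of its difference is not known. The macrophage list split 6 above and 6 below 0 (adjusted p = 0.617), with Lyz1 at 0.41. No member of these 7 lists passed, adjusted over the list alone or over all probes. The genes next to Abcg8 on chromosome 17 had 14 of 20 members below 0, with a mean of -0.19 (camera adjusted p = 0.0709). Of the 25 lists tested, the extracellular matrix list was the 1 that passed, and under median scaling, where the median difference of all probes was 0.11 log2 units, the chromosome 17 neighbours passed too, with 2 lists in all, as they did without wild-type replicate 2 or either ezetimibe array.

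The calls of single probes were lost with fewer arrays, while the differences stayed: with each array left out in turn Abcg8 differed by 3.71 to 4.04 log2 units, and over all alternatives probe 637213 by -4.64 to -4.26. The values of probe 637213 are set against a signal not detected on the knockout-labelled arrays, so they do not measure the size of its fall. The count of 2 became 0 without wild-type replicate 2, either knockout array or either ezetimibe array, and without wild-type replicate 1 it was 2, but these were other probes, with neither Abcg8 nor probe 637213 among them (the adjusted p of Abcg8 was 0.0611 there, and 0.0611 to 0.34 over the 6 arrays left out in turn). It became 0 with no filter on dim probes, and 31 when the prior variance followed the signal intensity, with Ston1 (adjusted p = 0.000302), Wdfy1 (adjusted p = 0.000302), Entpd4 (adjusted p = 0.000551) and Ctla2a (adjusted p = 0.0448) among them. With the 4 knockout-labelled arrays set together, a choice made after seeing the data, Ston1 was called too (adjusted p = 0.0218).

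**Figure D1:**
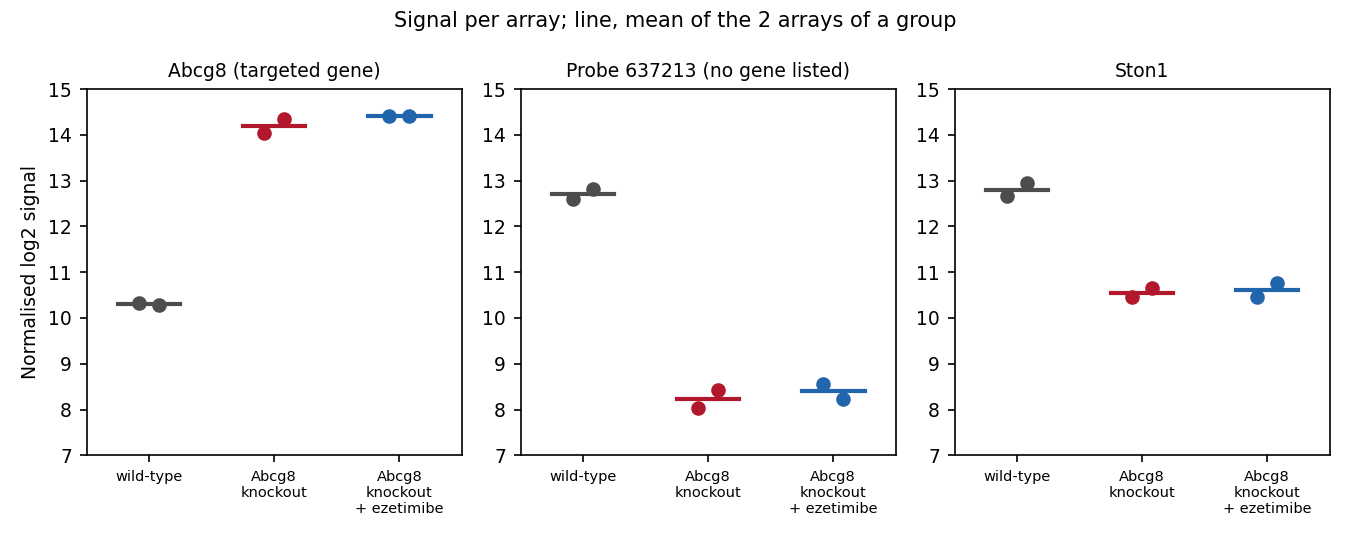
Normalised log2 signal (y axis) of Abcg8, of probe 637213 and of Ston1 on each of the 6 arrays (points), by group (x axis), with the mean of the 2 arrays of a group as a line. The Abcg8 means are 10.31, 14.19 and 14.41 in the order wild-type, knockout, knockout with ezetimibe, and the probe 637213 means are 12.71, 8.24 and 8.40.

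The next comparison asked what changed in knockout testes when sterol uptake from the gut was blocked with ezetimibe. Collagen, macrophage, Leydig cell and Sertoli cell genes were lower as groups in the ezetimibe arrays, while no single probe passed. Of 13 extracellular matrix and fibroblast genes, 11 lay below 0, with a mean of -0.45 log2 units (camera adjusted p = 3.66e-06). Of 12 macrophage genes, 10 lay below 0, with a mean of -0.24 (adjusted p = 0.000265). Of 12 Leydig cell and steroidogenesis genes, 10 lay below 0, with a mean of -0.24 (adjusted p = 0.000538). Of 15 Sertoli cell genes, 13 lay below 0, with a mean of -0.18 (adjusted p = 0.0276). The first 3 of these had adjusted p = 0.289 with an estimated correlation, and the Sertoli cell list had adjusted p = 0.545 with an estimated correlation.

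Within the matrix list, Col3a1 differed by -1.07 (SE 0.17), Col1a2 by -0.67 (SE 0.14) and Col6a1 by -0.56 (SE 0.12), and these 3 passed when adjusted over the list alone. Within the macrophage list, the complement gene C1qa differed by -0.40 (SE 0.10), C1qc by -0.44 (SE 0.10) and the lysozyme gene Lyz1 by -0.60 (SE 0.12), and these 3 passed when adjusted over the list alone. In the Leydig cell list, Cyp11a1 differed by -0.67 (SE 0.14), Hsd17b3, which makes testosterone, by -0.52 (SE 0.16, and -0.32 without ezetimibe replicate 2), Tspo by -0.42 and Hsd3b6 by -0.39, and 0 of 12 passed when adjusted over the list alone. In the Sertoli cell list, Fshr differed by -0.69 (SE 0.18) and Clu by -0.20, with 0 of 15 passing when adjusted over the list alone. None of these genes passed over all probes, where the adjusted p of Col3a1 was 0.495 with limma. Hba-a1 differed by -2.43 log2 units on the same arrays (limma adjusted p = 0.495) and Alas2 by -0.44 (adjusted p = 0.876).

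Among single probes, limma called 0 of 16015, while 922 had an unadjusted p under 0.05 and 801 would by chance; the lowest adjusted p was 0.444. Abcg8 differed by 0.22 log2 units (SE 0.13, limma adjusted p = 0.913), and Abcg5 was not detected. Among genes with a higher signal, none of which passed, Dcpp1 was not detected without ezetimibe and was at least 2.08-fold higher (adjusted p = 0.444), and Fyco1 differed by 1.10 log2 units and Cdk19 by 0.81. Among genes with a lower signal, Pou3f1 and Sfxn3 were not detected with ezetimibe and were at least 2.79-fold and 3.88-fold lower (limma adjusted p = 0.444 and 0.45). Necap1 differed by -1.13, and the tissue kallikrein genes Klk1b24 and Klk1b21 by -1.10 (SE 0.15) and -0.74 (SE 0.10). When the prior variance followed the signal intensity, 14 probes were called, all lower with ezetimibe, among them Klk1b21, Klk1b24, Col3a1, Hba-a1 and Apoe.

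The sterol lists did not pass with ezetimibe. Of 14 cholesterol synthesis and uptake genes, 9 lay above 0 and 5 below, with a mean of 0.04 (camera adjusted p = 0.776), Mvd at -0.39 and Tm7sf2 at 0.35 (0.19 without ezetimibe replicate 2), and 0 passed when adjusted over the list alone. Of 8 LXR targets and sterol efflux genes, 3 lay above 0 and 5 below (adjusted p = 0.341), and Apoe, a lipid-carrying apolipoprotein, at -0.72 (SE 0.14), was the 1 that passed when adjusted over the list alone. Apoc1 differed by -0.61 (-0.84 to -0.39 over all alternatives). The spermatogonia, spermatocyte, round spermatid and elongating spermatid lists had camera adjusted p of 0.658, 0.658, 0.573 and 0.396, with 6 of 13, 7 of 18, 13 of 20 and 12 of 18 members above 0 and 0 members passing when adjusted over each list alone. Members of these lists read -0.27 log2 units for Dazl, 0.21 for Hormad1, -0.20 for Catsper3 and 0.26 for Fscn3. No list passed with an estimated correlation, and fry, which tests whether a list moves one way on balance, called 0 lists. Without knockout replicate 1 the Leydig cell and Sertoli cell lists did not pass and the endothelium list did, and without either ezetimibe array, or with no filter on dim probes, the Sertoli cell list did not pass, leaving 3 lists each time.

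**Figure D2:**
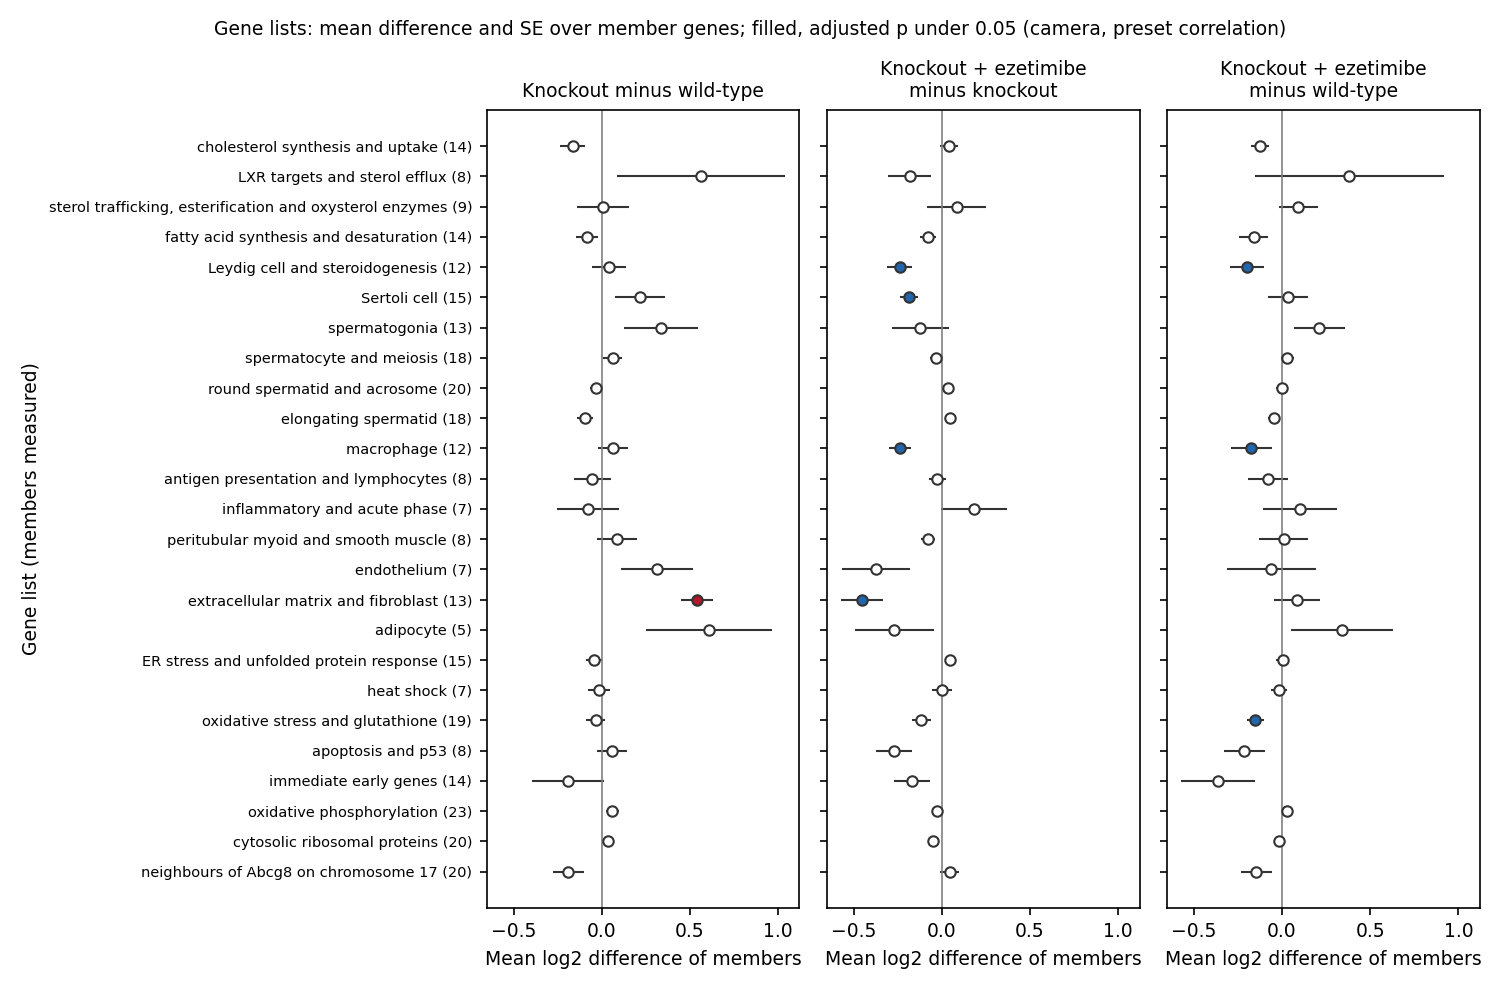
Mean log2 difference of the measured members of each of 25 gene lists (x axis, log2 units) in the 3 comparisons, with the number of members measured beside each list's name; bars are the SE over member genes and filled points passed camera with a preset correlation. The extracellular matrix list stands at 0.54 in knockout minus wild-type, at -0.45 in ezetimibe minus knockout and at 0.09 in ezetimibe minus wild-type.

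The last comparison set the ezetimibe-fed knockout-labelled testes against the wild-type-labelled testes. Abcg8 and probe 637213 changed again: Abcg8 was higher by 4.10 log2 units (SE 0.13, 17.1-fold, limma adjusted p = 0.0135), and probe 637213 fell by 4.31 log2 units (SE 0.19, limma adjusted p = 0.0346). Leydig cell, macrophage and glutathione genes were lower as groups. Of 12 Leydig cell genes, 10 lay below 0, with a mean of -0.20 (camera adjusted p = 0.0156), which ranged from -0.28 to -0.12 over the alternatives. Hsd3b6, a steroid dehydrogenase of adult Leydig cells, at -0.87 (SE 0.10), was the 1 that passed when adjusted over the list alone, and Hsd17b3 read -0.55 (-0.34 without ezetimibe replicate 2). Of 19 oxidative stress and glutathione genes, 16 lay below 0, with a mean of -0.15 (adjusted p = 0.0156), and 0 passed when adjusted over the list alone. Among them were Gpx3 at -0.59 (-0.80 to -0.38 over all alternatives), Gsta3 at -0.47 (-0.64 to -0.30) and Sod3 at -0.27. Of 12 macrophage genes, 9 lay below 0, with a mean of -0.17 (adjusted p = 0.039), and C1qc at -0.63, C1qa at -0.49 and Ctss at -0.44 passed when adjusted over the list alone. All 3 lists had adjusted p = 0.495 with an estimated correlation, and fry kept the glutathione list alone (adjusted p = 0.0231).

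The matrix list stood close to wild-type, with 6 of 13 members above 0 and a mean of 0.09 (camera adjusted p = 0.986), and Hba-a1 differed by -0.58 log2 units (limma adjusted p = 0.803). Of 14 cholesterol genes, 11 lay below 0, with a mean of -0.13 (camera adjusted p = 0.21), and Mvd, at -0.50 (SE 0.09), was the 1 that passed when adjusted over the list alone. The LXR list had 4 members above and 4 below 0 (adjusted p = 0.96), with Apoe at -0.48 and Srebf1 at -0.26, and Abcg8 was the 1 that passed when adjusted over the list alone. The Sertoli cell list and the 4 germ cell lists had adjusted p of 0.757 or more. Among the spermatogonia genes, Sohlh1 read 1.49 (1.01 to 1.97 over all alternatives) and Kit 0.68 (0.46 to 0.91). In these 5 lists 0 members passed when adjusted over each list alone. Ston1 at -2.19 (SE 0.17, limma adjusted p = 0.143) and Speer4d at 0.99 (adjusted p = 0.166) did not pass, nor did Entpd4 (adjusted p = 0.166). Egr1 and Sfrp2 were not detected with ezetimibe and were at least 5.37-fold and 3.61-fold lower (limma adjusted p = 0.143 for both).

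The 2 probes were all that limma called among 16015, with 1160 at an unadjusted p under 0.05 and 801 by chance. The count was 0 without wild-type replicate 2, either knockout array or either ezetimibe array, was 2 without wild-type replicate 1, again other probes, with neither Abcg8 nor probe 637213 among them (for Abcg8 adjusted p = 0.0645, and 0.0645 to 0.153 over the 6 arrays left out in turn, at a difference of 4.08 to 4.12 log2 units), and was 26 when the prior variance followed the signal intensity, with Ston1, Wdfy1, Entpd4 and Speer4d among them. The macrophage list no longer passed when any 1 of the 6 arrays was left out. The number of lists was 0 without wild-type replicate 1 and 1, the Leydig cell list, without wild-type replicate 2, while the glutathione list was also lost without ezetimibe replicate 2 and the Leydig cell list without ezetimibe replicate 1.

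The 3 groups were also tested together, and the moderated F-test called 2 probes, with 1225 at an unadjusted p under 0.05. No probe was called both in knockout against wild-type and, the opposite way, in ezetimibe against knockout. At an unadjusted p under 0.05, 176 probes were higher in knockout-labelled testes and lower with ezetimibe, and 166 were lower and then higher. Unchanged groups that share the 2 knockout arrays gave 110 on average in each direction in 100 simulations, with at most 141 and 134, and independent lists would give 24.4 and 17.3. Probes that moved the same way in both comparisons numbered 24, against 10.0 on average in the simulations. The simulated probes were independent of each other, and each varied alike on all arrays, wild-type replicate 2 included. Counts above the simulated ones thus cannot show a real excess. They were also not confined to probes moved back by ezetimibe. Across probes the 2 sets of log2 differences correlated with r = -0.47, and the simulations gave -0.53 to -0.46. Their covariance was -0.065, against -0.034 in the simulations and -0.039 from the spread of the 2 knockout arrays alone, a choice made after seeing the data. The covariance beyond that spread was -0.026, an estimate that rests on the 2 knockout arrays. A split of these arrays between the comparisons was not made. Part of the difference from the simulations may come from the shared arrays.

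**Figure D3:**
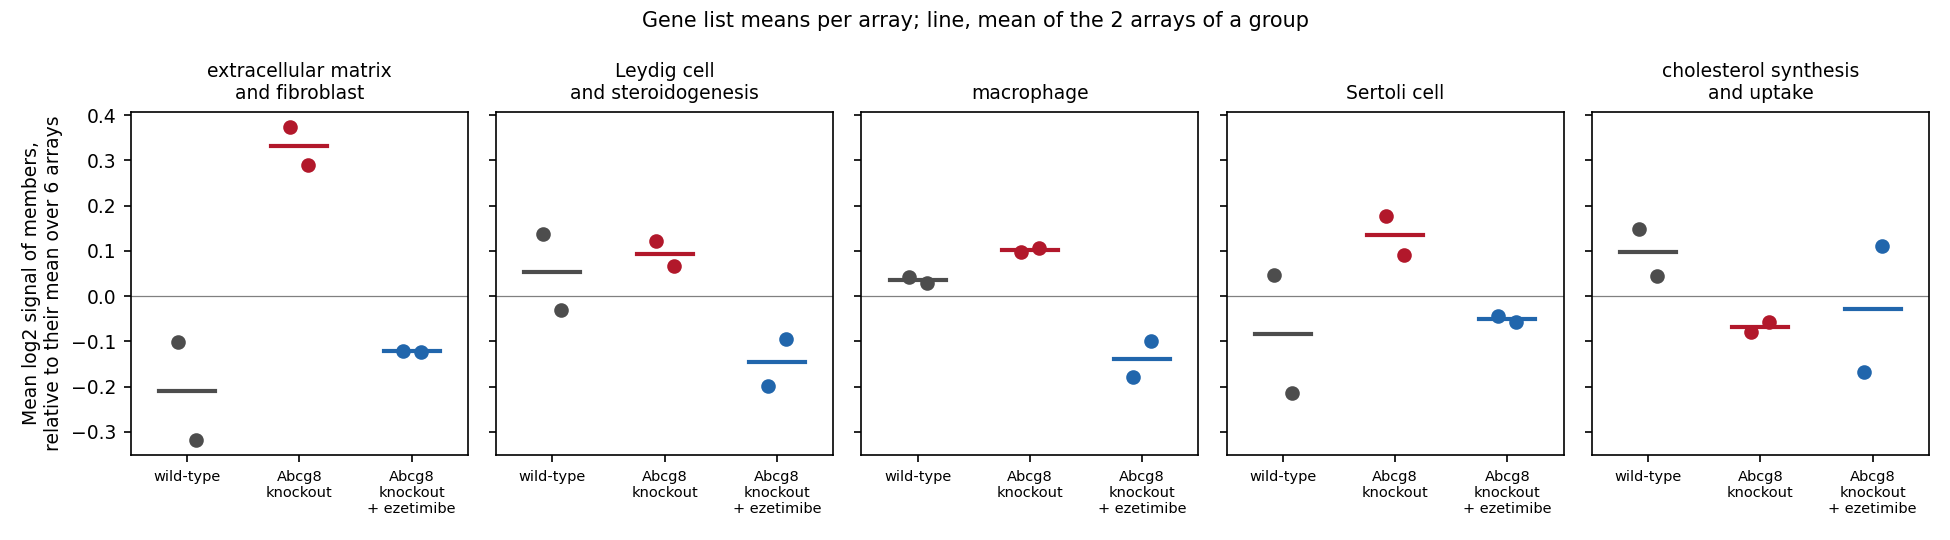
Mean log2 signal of the members of 5 gene lists on each array (points; y axis, log2 units relative to the mean over the 6 arrays), by group (x axis), with the mean of the 2 arrays of a group as a line. The extracellular matrix list reads 0.37 and 0.29 on the knockout arrays and -0.32 to -0.10 on the other 4.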

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

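The alternatives chosen only after seeing the data were the LXR list without Abcg8, the 4 knockout-labelled arrays set together against the 2 wild-type-labelled arrays, and the spread of the knockout arrays alone for the covariance. The count of 2 probes for knockout minus wild-type became 0 with no filter on dim probes, 4 with probes detected on all arrays, 31 with an intensity trend in the prior variance, 0 with only the 2 groups compared and 3 with the 4 knockout-labelled arrays together, Ston1 among them, and ranged from 0 to 2 when each array was left out in turn. For ezetimibe minus knockout, 0 became 14 with the trend (922 at an unadjusted p under 0.05 with limma). For ezetimibe minus wild-type, 2 became 0 with no filter, 26 with the trend, 1 with array weights and 1 with only the 2 groups compared, with 0 to 2 when arrays were left out. The F-test's 2 became 0 with no filter, 38 with the trend and 1 with array weights, and 0 to 0 when arrays were left out. The probes moved back by ezetimibe went from 0 to 5 with the trend. Left-out arrays leave fewer samples, and no filter tests more probes; the cause of the other differences was not tested.

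Lists past the threshold went from 1 to 2 for knockout minus wild-type under median scaling, with the authors' processed values and with probes detected on all arrays, and to 0 with an estimated correlation and 0 with fry, with 1 to 2 when arrays were left out. For ezetimibe minus knockout, 4 became 0 with an estimated correlation and 0 with fry. For ezetimibe minus wild-type, 3 became 0 with an estimated correlation and 1 with fry, with 0 to 3 when arrays were left out. The mixed test of fry, for members that change in either direction, called 11, 5 and 9 lists in the 3 comparisons in this order. The extracellular matrix list kept its call in both of its comparisons under every setting that was run with camera at the preset correlation. The cause was not tested.

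Of 2068 values of single genes and probes under alternatives, 2016 kept direction and side of the threshold, 29 lost a call, 16 gained a call and 7 reversed. Most of the 150 results did not pass and so had no call to lose. The 29 lost calls all fell on Abcg8 and probe 637213, the 2 probes that had been called. Of the 150 results, 67 moved by more than 1.5 times under at least 1 alternative. Nr1h3 in knockout minus wild-type read 0.015 under median scaling and 0.016 with the authors' values. With arrays left out, ezetimibe minus knockout ranged from -0.011 to 0.38 for Pgk2 and from -0.038 to 0.35 for probe 637213, and ezetimibe minus wild-type from -0.97 to 0.059 for Hsd17b7 and from -0.54 to 0.0054 for Prm2. The LXR list's mean in ezetimibe minus wild-type was -0.15 without Abcg8, whose own rise held the mean above 0. The cause was not tested for the others.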

Other observations

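The tests of the Abcg8 probe and of the extracellular matrix list were chosen only after the result was seen, as was the count of neighbour pairs shared between fits, and so were the genes Hba-a1, Hba-x, Alas2, Mcfd2 and Ttc7 and the Klk1b and Speer4 genes named here, except Klk1b21, Klk1b24 and Speer4d. In the fit with an intensity trend in the prior variance, 2 of 9 measured kallikrein genes of the Klk1b group were called in knockout minus wild-type and, the opposite way, with ezetimibe: Klk1b21 at 0.55 and then -0.74 log2 units (limma adjusted p = 0.0286 and 0.00843) and Klk1b27 at 1.01 and then -1.16 (adjusted p = 0.0294 and 0.0149). The 2 comparisons share the knockout arrays, which by itself favours opposite calls. In this fit 5 probes were called in opposite directions, the others being Hba-a1, Col3a1 and probe 719563. Unchanged groups in 100 simulations gave 0.01 such probes on average and at most 1. Those groups held no difference at all, so the simulations cannot say how many opposite calls shared arrays give where groups differ. Klk1b24 fell by 1.10 with ezetimibe (adjusted p = 0.00843). The other 6 were called in no comparison and went both ways, with Klk1b1 at 1.03 and then -0.83, Klk1b9 at -0.44 and then 0.18, Klk1b11 at -0.11 and 0.13, Klk1b26 at -0.13 and 0.11, Klk1b5 at 0.08 and 0.16 and Klk1b8 at -0.06 and 0.02. In the same fit, Speer4d and Speer4b were higher than in wild-type-labelled testes on both diets, at 0.69 and 0.99 (limma adjusted p = 0.00941 and 0.000508) and at 0.91 and 1.01 (adjusted p = 0.00941 and 0.0033). Speer4a passed with ezetimibe alone (0.80, adjusted p = 0.00948, against 0.56, adjusted p = 0.0883), and Speer4f1 in neither (0.14 and -0.14). None of these genes passed without the trend, and neither group was a list fixed in advance.

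The 3 lists too short to test had these means on the arrays in the order wild-type, knockout and ezetimibe, 2 each, relative to the mean over 6 arrays. The erythroid list of 2 genes, Hba-a1 and Alas2, read -0.12, -0.34, 1.10, 0.57, -0.84 and -0.37. The interferon response list of 3 genes read -0.20, -0.07, 0.06, 0.39, 0.02 and -0.20, and the epididymis list of 4 genes read 0.13, -0.12, 0.07, 0.07, -0.23 and 0.08.

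The Abcg8 probe was brighter on the arrays labelled knockout. The dim wild-type array is argued against as the cause, since without it the difference was 3.86 log2 units. A single exchange of arrays between the labels is argued against by the gap of 3.70 log2 units between the highest wild-type-labelled and the lowest knockout-labelled array. An exchange of the wild-type and knockout labels as whole groups is argued against by the ezetimibe arrays. These would stay knockout, yet their log2 signal was 14.42 and 14.40. The supposed wild-type arrays would then read 14.04 and 14.35, and the supposed knockout arrays on chow 10.34 and 10.29. An exchange of the wild-type and ezetimibe labels would likewise leave bright knockout arrays, at 14.04 and 14.35. This rests on the Abcg8 probe alone and assumes that its signal follows genotype alike on both diets. No other gene of known direction was fixed, so the test set for an exchange of whole groups could not decide. Transcription through the altered gene outside its changed part may give this signal, as an untested hypothesis that rests on 1 probe.

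The extracellular matrix list was higher in knockout-labelled testes and lower with ezetimibe, with camera adjusted p = 0.656 and 0.289 when the correlation was estimated. Both comparisons use the same 2 knockout arrays, so a deviation of these arrays alone would give both shifts. Without the dim wild-type array its mean difference from wild-type was 0.44, against that array as the whole cause. A larger share of all interstitial tissue in knockout-labelled testes is argued against as the whole cause, since the matrix genes shifted by 0.54 and the 39 genes of the Leydig, macrophage, endothelium and peritubular lists by 0.11 (permutation p over genes of 0.00043), although genes are not independent replicates. The matrix list was picked as the only list that passed here, and this p takes no account of that choice. With ezetimibe a smaller share stays open: those 39 genes were lower too, at -0.23 against -0.45 (permutation p = 0.0367), and the gap of -0.22 lay within the SD over genes of 0.42 and 0.29. A different amount of blood, given the values of Hba-a1, may contribute and was not tested, nor was an effect of genotype and diet on collagen genes themselves. Alas2 differed by 0.27 and then -0.44. Hba-x went the other way, but it was not detected in knockout-labelled testes, so the size of its differences is not known.

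Among the 100 genes with the lowest p between the 4 knockout-labelled and the 2 wild-type-labelled arrays, 12 pairs lay within 5 measured genes of each other on a chromosome of assembly GRCm38.p6, against a median of 6 and a 95th percentile of 10 in 10000 random draws (permutation p = 0.0177), among them Ston1 with Mcfd2 on chromosome 17. Without the dim wild-type array there were again 12 pairs (permutation p = 0.0128), but 1 pair was found both times, and Ston1 was then paired with another neighbour, Ttc7 (-2.08 and -1.84 log2 units), so the limits set in advance on the count alone were too weak and that array stays open as a source of the pairs. Chromosome segments kept from a donor strain may give such pairs, as a hypothesis, and stay open: 9 of the 100 genes lay on chromosome 17 in both fits, which held 5.09% of the placed genes, while outside the Speer4 cluster 9 pairs were left with all arrays and 11 without the dim one, below and above the 95th percentile of 10. Cross-hybridisation within gene families stays open too, since 2 of 12 pairs shared a name with all arrays and 5 of 12 without the dim one.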
